A study of Schmidtea mediterranea with 9 samples.

How the data were processed

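Libraries of poly(A) RNA from sorted planarian neoblasts were sequenced on an Illumina platform, per the labels' protocols. The submitters' processing notes name Bowtie2 2.0, SAMtools and DESeq, with no version for the last pair. The assembly the reads were aligned to is not given in the sources used here beyond its contig identifiers. The authors deposited for each library a file of read counts per contig, with the contig length and the unmapped reads. A further deposited file gives counts per component, in which the authors summed contigs of the same component. A deposited DESeq table gives, per the file headers, the authors' mean normalized signal per group, the ratio (fold change) and the p-value and adjusted p-value for each wound against the control. The logarithm columns of that table hold an error text in some cells, so the logarithm was taken of the ratio. The other quantity per the file headers is the contig length in bases.

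Samples were grouped by their titles into the 0 h control, the anterior wound and the posterior wound, 3 libraries each. The labels do not say that replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom between 7.27 and 75.5), so none was counted as a repeat of another.

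The deposited summed counts were compared with sums made from the per-library counts. Of the 46724 components, 39535 have 1 contig and 7189 have several. In 8 of the 9 columns the deposited table equals the sums of a library of the column's group for every component. In the column of posterior replicate 3, all 7189 summed components hold the values of posterior replicate 2, while the components of 1 contig hold their own. The design fixed before the data were examined named the deposited summed table as the input. Because of the repeated column, the counts tested were instead summed from the per-library counts, and the deposited table became an alternative. The columns of the controls and 2 anterior columns that share a header entered that alternative by group only, with no replicate number. No column of per-library values was left without a sample or group (0). Unmapped reads stayed out of library sizes and tests.

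Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, the default filterByExpr filter (minimum count 10), 1 quasi-likelihood fit of the 3 groups over all 9 libraries, and Benjamini-Hochberg adjustment with calls at 0.05. The filter left 21322 components, which held between 99.5% and 99.8% of the mapped reads. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. The common coefficient of variation was 26.9%, and the median SE of a log2 fold change was 0.33, or 0.17 for components over 8 CPM. Levels are CPM scaled by TMM, and log2 levels used a prior count of 2.

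Components were named by a rule fixed before the data were examined: among calls at 0.05 with a mean of at least 2 CPM in the higher group and every replicate of 1 group above every replicate of the other, the largest rises and falls. Because the files do not pair components with names, the rule allowed 2 identifiers per direction and comparison. A component named outside it is said to be chosen after its values were seen. The 18 gene lists fixed before the data were examined cover neoblast, replication, mitosis, wound, position and lineage genes, genes of other cell types, and housekeeping and stress genes. With no names to match, 0 of them could be tested.

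The test was tried on simulated data, with 200 components changed per comparison, 50 at each of 4 sizes. Counts were drawn from each component's mean CPM over all 9 libraries and its estimated dispersion. Draws were independent between components, so components that vary together were absent from these simulations. For the anterior wound, 20% of components changed 2-fold, 62% of those changed 4-fold and 78% of those changed 8-fold were recovered, with 8 false calls among 89. For the posterior wound these shares were 10%, 58% and 76%, with 3 false calls among 75. Between the wounds there were 8 false calls among 95.

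Alternatives were other scalings (DESeq2's size factors, upper quartile), no filter or a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a block for the replicate number, a fit of the 6 libraries of each comparison, each library left out in turn, contigs without summing, and a minimum log2 fold change of 1. Chosen after seeing the data were the deposited summed table, a score for long contigs as a covariate, the first principal component as a covariate, edgeR's older quasi-likelihood method, DESeq2 on the 6 libraries of each comparison without independent filtering, removal of the most abundant component, removal of control replicate 1 with posterior replicate 3, and removal of control replicate 3 with anterior replicate 2. The score for long contigs is the median log2 deviation of a library over the 501 components with a contig longer than 4000 bases.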

Results

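Poly(A) RNA was sequenced from dividing stem cells (neoblasts) of the planarian Schmidtea mediterranea, a flatworm that regrows missing body parts. The cells were sorted by flow cytometry from the region in front of the pharynx, as live cells with more than the diploid DNA content. There were 9 libraries in 3 groups of 3: uninjured animals (the 0 h control), animals whose head had been amputated 48 h earlier (anterior wound), and animals whose tail and pharynx had been amputated 48 h earlier (posterior wound). The comparisons ask which transcripts of neoblasts in the same body region change after a wound, and whether the site of the wound matters. No uninjured group was sampled at 48 h, so against the control an effect of the wound cannot be told apart from one of the elapsed time. Mapped reads numbered 14674800, 23375647 and 23700877 in control replicates 1 to 3. They numbered 20426337, 19779932 and 18612082 after the anterior wound, and 17017960, 17838410 and 19412889 after the posterior wound. Unmapped reads were 11.4% (95% Wilson interval 11.36 to 11.39%) of the reads of control replicate 1 and between 3.96% and 5.46% of those of the other libraries. The intervals cover counting error only.

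Reads were counted on 63423 assembled contigs, which fall into 46724 components, the assembler's unit closest to a gene. The files do not pair these components with gene names, so components are given by identifier. For the same reason the lists of neoblast, cell cycle, wound, position and lineage genes fixed in advance could not be matched to any component. Components with at least 1 read numbered from 36643 in posterior replicate 3 to 41869 in posterior replicate 2. The most abundant component, of 944 bases, took 9.19% of the mapped reads in control replicate 1 and 16.9% in control replicate 3, with the other libraries in between. A principal component analysis of the 21322 components tested did not separate the groups. The first component held 37.6% of the variance, with control replicate 1 (-71.9) and posterior replicate 3 (82.1) at its ends.

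After the anterior wound, 6 components rose and 0 fell against the 0 h control. The component comp11581_c0 (1307 bases) stood at 3.42 ± 1.02 CPM (counts scaled to library size; SD, n = 3) in the controls and at 15.6 ± 0.64 CPM (SD, n = 3) after the anterior wound. Its log2 fold change was 2.18 (SE 0.23, adjusted p = 0.0147). The component comp17960_c0 (803 bases) stood at 4.46 ± 0.25 CPM (SD, n = 3) in the controls and at 19.6 ± 1.48 CPM (SD, n = 3) after the wound, with a log2 fold change of 2.14 (SE 0.17, adjusted p = 0.0014). The 6 components rose between 2.65-fold and 4.53-fold, and at each of them every wounded library lay above every control library. Such a separation is common and adds little to a call. In either direction it held at 10.9% of all components tested, where chance gives 10%.

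These 6 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 21322 components. At an unadjusted p under 0.05, 819 components (3.84%) passed, where chance alone gives 1066.1. DESeq2 called 14 that rose and 11 that fell, among them all 6. Fitted to the 6 control and anterior libraries alone, edgeR called 1, which rose. No component fell by edgeR over the 9 libraries, where 568 components were lower at an unadjusted p under 0.05. Leaving out 1 library left between 1 and 4 calls, and every library moved the count by 1.5 times or more: it was 3 without control replicate 1, 1 without control replicate 2, 4 without control replicate 3, 1 without any 1 of the anterior replicates, and 2, 3 and 3 without posterior replicates 1, 2 and 3.

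After the posterior wound, 6 components rose and 0 fell against the same controls. The component comp1298_c0 (640 bases) stood at 8.19 ± 3.37 CPM (SD, n = 3) in the controls and at 58.1 ± 8.58 CPM (SD, n = 3) after the posterior wound. Its log2 fold change was 2.82 (SE 0.26, adjusted p = 0.00721). The component comp11581_c0 stood at 16.5 ± 2.02 CPM (SD, n = 3) after this wound, a log2 fold change of 2.25 (SE 0.23, adjusted p = 0.00721). The 6 components rose between 1.80-fold and 7.05-fold.

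At an unadjusted p under 0.05, 1270 components (5.96%) passed edgeR's test for the posterior wound, 562 higher and 708 lower, against the 1066.1 that chance gives. DESeq2 called 34 that rose and 22 that fell, including all 6 of the edgeR calls. Without control replicate 3, 265 components rose and 27 fell, and the 6 were among them. Without control replicate 2 the count was 2, and without control replicate 1 it was 9. It was 3 without any 1 of the anterior replicates, 2 without posterior replicate 1 and 3 without posterior replicate 2. Fitted to the 6 control and posterior libraries alone, edgeR called 0.

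**Figure D1:**
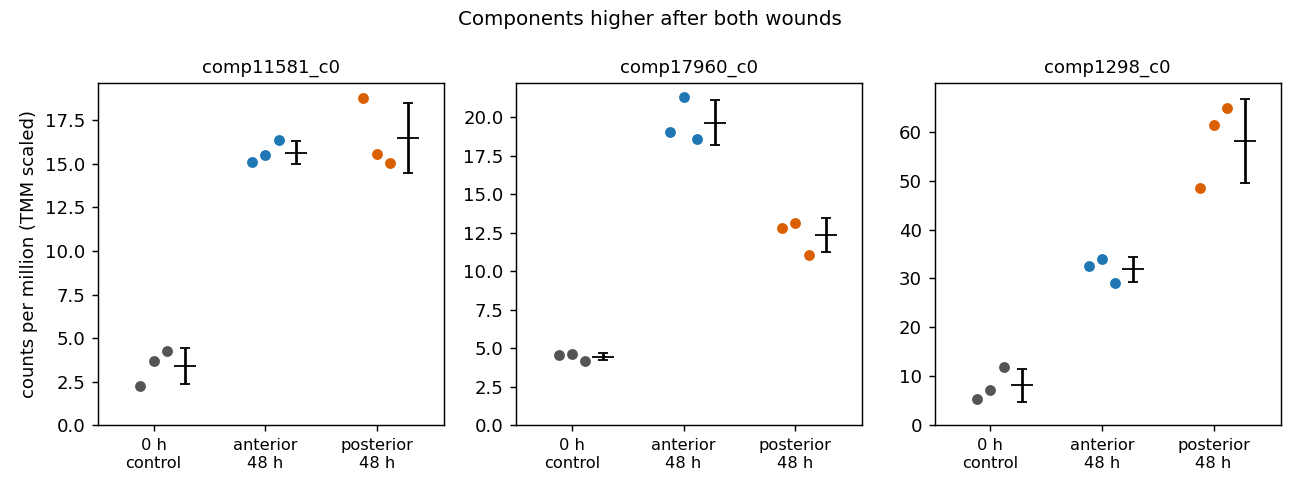
CPM (vertical axes, linear, from 0) of comp11581_c0, comp17960_c0 and comp1298_c0 in the 9 libraries. Points are the 3 replicates of each group, and the bar beside them is the mean with the SD. At each of the 3 components every wounded library lies above every control library, which the naming rule required for the wound that named it. The means of comp17960_c0 are 4.46 CPM in the controls, 19.6 CPM after the anterior wound and 12.3 CPM after the posterior wound.

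The components called in both wounds were 3, all higher: comp11581_c0, comp17960_c0 and comp1298_c0. The last had a log2 fold change of 1.95 (SE 0.25, adjusted p = 0.0423) after the anterior wound, and comp17960_c0 one of 1.47 (SE 0.16, adjusted p = 0.0105) after the posterior wound. The anterior call of comp1298_c0 was lost in 11 of 27 alternatives, among them leaving out any 1 library but control replicate 3 (adjusted p from 0.0879 to 0.262). The posterior call of comp17960_c0 was lost in 7, and the anterior and posterior calls of comp11581_c0 in 5 and 3. Independent lists of these sizes would share 0.00169 components. The count was 0 without control replicate 2, without any 1 of the anterior replicates or without posterior replicate 1. It was 1 without posterior replicate 2, 2 without posterior replicate 3, and 3 and 4 without control replicates 1 and 3; comp1298_c0 was not among the 3 without control replicate 1 (adjusted p = 0.0892 after the anterior wound). In 30 simulations of unchanged groups, with both wounds set against the same simulated controls, 0.0333 components rose in both on average, and at most 1. All 9 libraries, controls included, were drawn anew with 1 mean and 1 dispersion per component, independently between components. Differences in spread between the groups and components that vary together were thus absent from these simulations. The 3 components called only after the anterior wound were also higher after the posterior wound, by log2 0.40 to 1.45 (adjusted p from 0.0618 to 0.78). The 3 called only after the posterior wound were higher after the anterior wound by log2 0.57 to 1.29 (adjusted p from 0.0686 to 0.518).

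**Figure D2:**
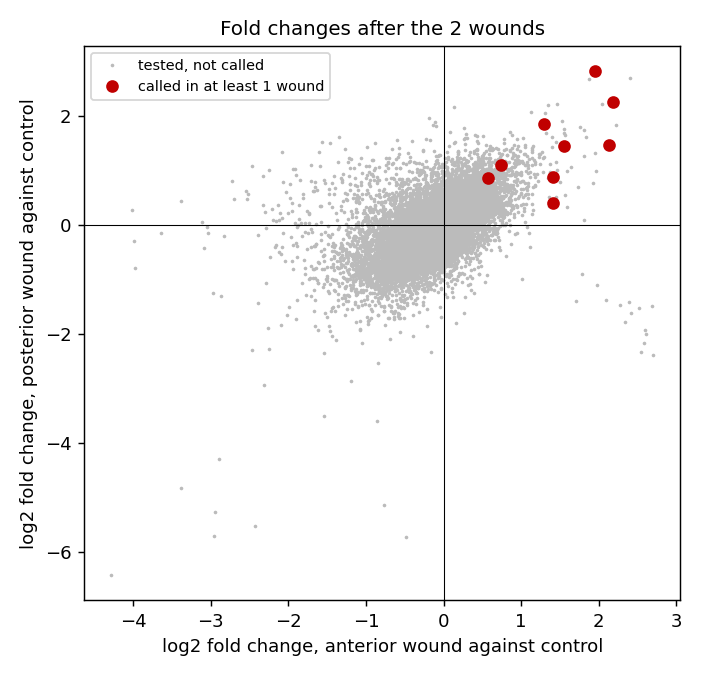
Log2 fold changes against the 0 h control of the 21322 components tested, after the anterior wound (horizontal axis) and the posterior wound (vertical axis). Red points are the 9 components called in at least 1 comparison, all of them above 0 on both axes; both axes use the same 3 control libraries.

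Across components, the fold changes of the wounds correlated with r = 0.556, and 76.4% had the same sign. Components are not independent replicates, and shared controls alone gave r = 0.495 and 66.6% in the simulations, whose controls were drawn as well. The covariance was 0.109, against 0.0887 in the simulations. With 3 control libraries, the controls cannot be divided so that each part keeps a pair, so part of the excess may come from the shared controls. Over the 8087 components above 8 CPM the covariance was 0.0645, and the spread of the controls alone gives 0.0590.

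Between the wounds, no component passed edgeR's test. The lowest adjusted p was 0.904, and 581 components (2.72%) had an unadjusted p under 0.05. limma-voom also called 0, with 581 at an unadjusted p under 0.05, whereas DESeq2 called 3 that were higher and 14 that were lower after the anterior wound. DESeq2 fitted to these 6 libraries alone without independent filtering, a setting added after seeing the data, called 6 that were higher and 75 that were lower, and edgeR fitted to these 6 libraries called 4 that were lower. At comp17960_c0 the anterior wound was higher by log2 0.67 (SE 0.16, adjusted p = 1.0), and at comp1298_c0 the difference was -0.87 (SE 0.24, adjusted p = 1.0), which passed only in that DESeq2 fit among the 27 alternatives (adjusted p = 0.00578, with a range from 0.00578 to 1.0 over them). Among the 9 components called against the control, 7 differed between the wounds when p was adjusted over those 9 alone, but the 9 were chosen on the same libraries, so this is not independent evidence. In simulated data of the same depth and spread, edgeR recovered 70% of 50 components changed 4-fold between the wounds. It recovered 24% of those changed 2-fold. These shares need not hold for the observed libraries, where 2.72% passed at an unadjusted p under 0.05 and chance gives 5%. Over all 9 libraries, DESeq2's 14 lower calls had log2 fold changes from -3.57 to -0.88, and its 3 higher calls from 1.00 to 5.57. At each of these calls edgeR's adjusted p was 0.904 or above. The absence of edgeR calls thus leaves open differences of 4-fold or more.

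The authors' deposited table of DESeq results called 9 components after the anterior wound, 8 higher and 1 lower. The 1 that was lower in the authors' deposited table, comp1712_c0, had a fold of 0.202 there (adjusted p = 0.00327). It is named here after its values were seen. By edgeR its log2 fold change was -2.29 (SE 0.45, adjusted p = 0.522), from 2.37 CPM in the controls to 0.472 CPM after the anterior wound and 2.25 CPM after the posterior wound. For the posterior wound the authors' deposited table called 23 components, 15 higher and 8 lower. Of the calls in the authors' deposited table, 6 of 9 and 5 of 23 were also called here. Log2 folds in the authors' deposited table correlated across components with those fitted here at r = 0.999 for the anterior wound and 0.947 for the posterior wound. Both sets of folds come from the same libraries, so these correlations are not independent evidence. The authors' posterior values rest on the summed counts in which posterior replicate 3 repeats replicate 2, and those fitted here do not.

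At a subset of components, control replicate 3 and anterior replicate 2 lay away from the rest of their groups. Over all components the measures differed. By chi-square per degree of freedom, control replicate 1 differed most from the other controls (50.2 and 75.5, against 28.4 between control replicates 2 and 3), and anterior replicates 2 and 3 were the closest anterior pair (11.6). On the first principal component control replicate 3 lay at 37.8, and control replicates 1 and 2 at -71.9 and -46.6. Among the 10 ways of dividing the 6 control and anterior libraries into 3 and 3, each in a fit that kept the posterior libraries as their own group, the one that puts anterior replicate 2 with control replicates 1 and 2 called 290 components, more than the 6 of the labelled groups, and the other 8 called 0. With both libraries left out, a fit chosen after seeing the data, 65 components were called after the anterior wound and 378 after the posterior wound. Of these, 62 rose in both, including the 3 named above. Placing each library between the mean of control replicates 1 and 2 (position 0) and that of anterior replicates 1 and 3 (position 1), control replicate 3 had a median position of 1.17 over the 62 components and anterior replicate 2 one of 0.20. At 4 of the 62, control replicate 3 lay at 0.40 or below and anterior replicate 2 at 0.99 or above. These 4 were all among the components called over the 9 libraries.

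**Figure D3:**
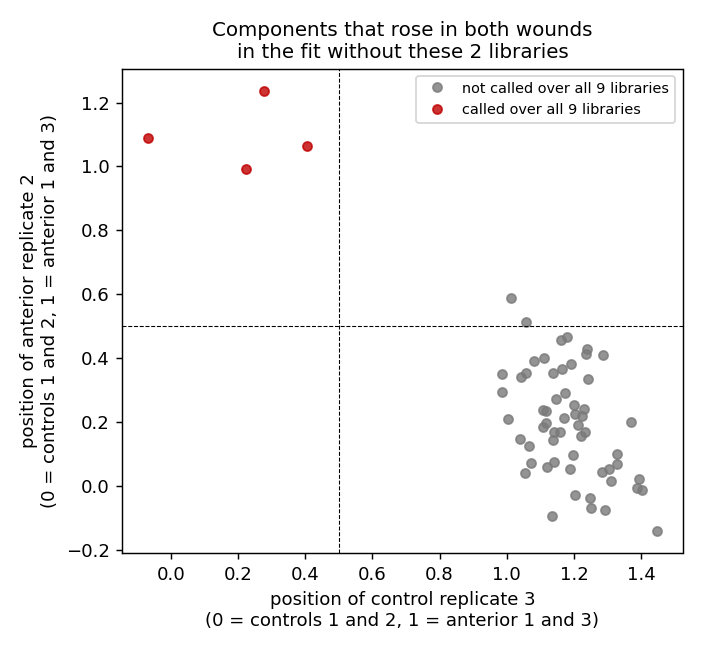
Positions of control replicate 3 (horizontal axis) and anterior replicate 2 (vertical axis) at the 62 components that rose in both wounds when these libraries were left out; 0 is the mean log2 level of control replicates 1 and 2 and 1 that of anterior replicates 1 and 3, and the dashed lines mark 0.5. At 56 components (lower right) control replicate 3 lies above 0.5 and anterior replicate 2 below it, at 4 (upper left, red) the reverse holds, and at the other 2 both lie above it.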

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

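Against the 6 components that rose after each wound, DESeq2 called 25 and 56, and a fit of the 6 libraries of each comparison called 1 and 0; between the wounds these gave 17 and 4, against 0. Components in both wounds, 3 over all libraries, were 9 by DESeq2, 0 with separate fits and 5 without a filter. Leaving out each library gave 1 to 4 after the anterior wound, 2 (without control replicate 2) to 292 (without control replicate 3) after the posterior wound, 0 between the wounds and 0 to 4 in both wounds. Of the alternatives chosen after seeing the data, leaving out control replicate 3 and anterior replicate 2 gave 65, 378 and 62 in both. DESeq2 on the 6 libraries of each comparison without independent filtering gave 11, 16, 81 between the wounds and 5 in both. The posterior count was 16 with the long-contig score, 13 with the first principal component, and 20 without control replicate 1 and posterior replicate 3. Separate fits rest on fewer samples. Explanations for the 292 are weighed under the other observations; for the remaining counts the cause was not tested.

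The fit with a replicate block called 5 after the anterior wound, 8 after the posterior wound, 0 between the wounds and 4 in both. The numbers do not pair the libraries throughout: 3 of 9 same-number pairs correlated above 0.1, and 4 of 9 libraries correlated best with their own number. The highest correlations were between control and posterior libraries of the same number, 0.45 for replicate 3 and 0.35 for replicate 2. Pairs of different numbers reached at most 0.24, and control and posterior replicate 1 correlated at 0.048.

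The rises of comp11581_c0, comp17960_c0 and comp1298_c0 kept their direction in all 27 alternatives. The adjusted p reached 0.132 and 0.166 for comp11581_c0 (anterior, posterior), 0.333 and 0.0909 for comp1298_c0, and 0.0213 and 0.269 for comp17960_c0. The difference between the wounds at comp11581_c0 was -0.07 over all libraries and ranged from -0.13 to 0.034 with each library left out, the last without posterior replicate 1, and was never called. Other scalings moved the median fold change by less than 0.1. The gene lists and their alternatives were not run.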

Other observations

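All explanations weighed here were tested after the counts they concern had been seen, except the test of the long-contig score without control replicate 3, whose bounds were written first.

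Several sets of components that varied within groups also varied together over all libraries, by thresholds chosen after seeing the data. The correlations used to cluster them include differences between the groups. Their levels are given as CPM of all mapped reads, without TMM scaling. Of 192 components with a mean over 1 and a within-group SD over 1 on the log2 CPM scale, clustering at a correlation over 0.9 gave 4 sets of at least 5 components. The largest, of 58, stood at 188.7, 104.3 and 870.1 CPM in control replicates 1 to 3, at 528.7, 122.8 and 551.5 after the anterior wound, and at 807.7, 770.4 and 952.3 after the posterior wound. A set of 47 was at 677.6, 657.6 and 164.6 CPM in control replicates 1 to 3, and highest at 756.0 CPM in posterior replicate 2 and lowest at 72.8 CPM in posterior replicate 3. A set of 6 components held 45339 reads in anterior replicate 1 and 8100 in control replicate 2, and between 126 and 1669 in the other libraries. A set of 40 was highest in control replicate 2 (1633.5 CPM), anterior replicate 1 (1298.1) and posterior replicate 2 (1204.8), and at 123.4 in posterior replicate 3. Of the set of 58, 44 are among the components that rose in the division of the libraries weighed next, so it is largely the same signal. For the other 3 sets no explanation was tested, and the files give no names for the members of any.

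Without control replicate 3 the posterior wound had 292 calls. The 290 components called by the division that puts anterior replicate 2 with control replicates 1 and 2 include 130 of the 265 that rose. Both lists set control replicates 1 and 2 on the low side, and the overlap that these shared libraries give alone was not computed. A candidate explanation is that control replicate 3 and anterior replicate 2 carry each other's label: over the 62 components chosen without either library, the median position of anterior replicate 2 was 0.20, near the controls, and that of control replicate 3 was 1.17. Over 291 of the 292 calls, placed between control replicates 1 and 2 (0) and the posterior libraries (1), anterior replicate 2 was less near the controls. Its median position was 0.36, against 0.78 for anterior replicates 1 and 3 and 1.00 for control replicate 3. Components that vary together are not separate pieces of evidence. Against an exchange of labels stand 4 of the 62 components, at which both libraries lie with their labelled groups. An exchange alone leaves these 4 unexplained, while correct labels leave the other components to some difference between libraries that the groups do not give. Both remain open, and no biological explanation was tested.

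Recovery of long transcripts is a further possible explanation, and these data leave it undecided. With the long-contig score in the fit, the posterior calls without control replicate 3 fell to 7, but the score shuffled over the libraries left 7 or fewer in 17 of 30 draws and between 9 and 1697 in the other 13 (median 6). A fall of this size was thus common with shuffled scores, and the fall cannot be told apart from that given by an unrelated covariate. The bound written first, at most 2 times the posterior count over all libraries, was met by the 7. The comparison with shuffled scores was added after the fall was seen, and it is what leaves this explanation undecided. Across the 9 libraries the score correlated with the first principal component of the other components (r = -0.97, exact permutation p = 2.2e-05, adjusted 4.41e-05; rho = -0.97, exact permutation p = 0.000165, adjusted 0.000331), and r was -0.93 without the 2 libraries farthest from the median score. Other sets of components were not set beside the first principal component, so that relation does not single out long contigs. With the median level of the components that rose, r was -0.76 (exact permutation p = 0.0178, adjusted 0.0178) and rho -0.73 (exact permutation p = 0.0311, adjusted 0.0311), over 2 relations computed. Without the 2 libraries farthest from the median score r fell to -0.53, so this relation rests partly on them. Control replicate 1 (score 0.31, level -1.13) and posterior replicate 3 (-0.34, 0.76) followed it. Control replicate 2 and posterior replicate 2 had similar scores (0.18 and 0.20) but levels of -0.92 and 0.39, a difference the score does not give. The components that rose had a median length of 707 bases, against 754 for all tested, and 1 was longer than 4000 bases. These components were called as low in control replicates 1 and 2 and high after the posterior wound. Their levels were thus partly fixed by that choice, which the permutations ignored.

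In the authors' deposited table, 8 of the 23 posterior calls were summed components, which make up 15.4% of all components (Fisher's exact test, two-sided p = 0.0202), against 0 of 9 anterior calls. A candidate cause is that posterior replicate 3 repeats replicate 2 in the summed IDs: the posterior means of the authors' deposited table follow from the deposited columns with a largest relative residual of 1.39e-09, and from the per-library columns with one of 2.87. Fitted to the 6 control and posterior libraries without independent filtering, not to all 9 as for the 56 calls of the report, DESeq2 called with the deposited column 12 summed and 18 single-contig components, and with the per-library counts 6 and 10, so calls of both kinds fell although the counts of single-contig components are identical in both. The summed share of the calls was 40% with the deposited column and 37.5% (Fisher's exact test, two-sided p = 0.0296) with the per-library counts. By DESeq2 an excess over the share among all components with an adjusted p (15.8%) was thus still there without the repeat. The share among components with similar read counts was not computed, so the excess was not set against components equally likely to be called. By edgeR, 2 of 8 calls were summed components with the deposited column and 0 of 6 with the per-library counts, and the coefficient of variation of summed components in the posterior group was 7.93% with the repeat and 22.99% without it. The repeat thus entered the authors' deposited table, but these counts leave open whether it gave the excess.

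The 6 libraries of each comparison can be divided in 10 ways, too few for a share under 0.05. Each division was fitted with all 9 libraries, the third group kept as labelled; fits of the 6 libraries alone called 1 for the anterior wound, 0 for the posterior wound and 4 between the wounds with the labelled groups, and their other divisions were not run. For the anterior wound the labelled groups called 6 and the highest other division 290, so 2 of the 10 gave at least 6, and the larger count points to a structure of the libraries that the groups do not follow. For the posterior wound the labelled groups called 6 and the highest other division 0, with 1 of the 10 giving as many. Between the wounds all 10 divisions called 0.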
